A study of Mus musculus with 15 samples.

How the data were processed

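The series holds 15 ATAC-seq libraries, each from 40000 islet cells of a male mouse and sequenced as single-end reads of 75 bp, per the labels' protocols. Mice received doxycycline at 1 g/L in drinking water for 2 weeks, and PPx followed 1 week after its withdrawal, per the labels' protocols. Groups were taken from the sample titles: control before PPx (4), KO-labelled before PPx (3), control after PPx (4) and KO-labelled after PPx (4).

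Reads were handled with cutadapt, BWA, MACS, DiffBind and ChIPseeker on the mm10 build, per the submitters' processing notes, which give no versions, roles or settings in the sources used here. The authors deposited 4 tables, one per comparison, each listing peaks of 601 bp called in at least 2 libraries of the comparison. The deposited concentrations are log2 values of normalised reads per peak, averaged over each group, and the deposited fold is the difference of the log2 group means. The scaling between libraries is not given in the sources used here. Each deposited row has a p-value and an FDR from the authors' test, whose method is not named in the file headers. In the deposited tables, counts give the number of libraries of each group in which the peak was called. Gene symbols, gene identifiers and annotation (promoter as within 3 kb of a transcription start site, exon, intron, distal) are those of the deposited tables, and gene symbols were matched exactly.

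Depth per library, values per library and the spread between single libraries are not analysed here, because the tables hold group means only. A p-value of the authors' test was read as measuring spread between libraries, with 3 or 4 mice per group. The method of that test is not named, and every implied standard error rests on this reading. The median standard error implied by fold and p was 0.43, 0.40, 0.38 and 0.49 log2 units in the tables of genotype before PPx, genotype after PPx, PPx in controls and PPx in KO-labelled islets.

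The tables had 9023, 18392, 9407 and 17355 rows in that order. Repeated rows were removed (1197, 5281, 1337 and 4588), as was 1 blank row of the first table, which left 7826, 13111, 8070 and 12767 peaks near 6682, 9846, 6742 and 9736 genes. Folds were turned to read as KO-labelled minus control and after minus before PPx. A peak was called gained or lost at the authors' FDR of 0.05 or below. In the 2 tables with the KO-labelled libraries taken after PPx, the deposited FDR is not a plain adjustment of the listed p: peaks of low concentration have an FDR of 1, at concentrations up to 3.50 and 3.19, and the Arid1a peak at 3.15 after PPx is an exception with an FDR of 0.00201. Of the peaks with an FDR of 1, 634 and 532 have an unadjusted p under 0.05. A deposited p of exactly 1 stood beside 7, 3, 6 and 2 peaks, which were left out of steps that need a standard error.

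The standard error of a fold was computed as its size divided by the two-sided normal quantile of the deposited p. For folds under 0.1 or p of 0.95 and above it was the median of 1 of 40 bins of mean concentration. Shares of promoter peaks among gained and lost calls were compared by two-sided Fisher's exact test. Peaks of different tables were matched by an overlap of at least 1 bp. The overlap of comparisons that share libraries was set beside 100 simulations of unchanged groups with the same sharing, which drew normal deviates with the correlation that 4 shared libraries give and were read at the largest p the authors called and at the observed list lengths. The difference of the effect of genotype between states was tested by a two-sided z test with Benjamini-Hochberg adjustment.

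For the 22 gene lists, which held 376 genes, the median fold of a list's peaks was compared with 100000 random gene sets of the same size, matched in 10 bins of peaks per gene, as a two-sided permutation test, adjusted by Benjamini-Hochberg over the lists of a comparison with at least 3 genes listed. The lists were beta cell identity, genes normally kept off in beta cells, islet progenitor and dedifferentiation genes, EGF and neuregulin ligands with ERBB receptors, ERBB-MAPK signalling and feedback, AP-1 factors, cell cycle drivers, cell cycle inhibitors, SWI/SNF subunits, insulin and IGF signalling, prolactin receptor signalling, TGF-beta and activin signalling, the unfolded protein response, the interferon and NF-kB response, and markers of alpha, delta and PP, acinar, ductal, endothelial, stellate and fibroblast, leukocyte and Schwann cells. Also adjusted over the list alone were the p-values of each list's peaks.

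Lists, tests, thresholds, most alternative settings and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, every Arid1a peak, the 8 gained and 8 lost peaks with the smallest FDR (1 per gene, without Gm, Rik and Mir genes), and up to 3 genes with a called peak from each list that passed and from the beta cell identity, EGF and neuregulin, cell cycle and SWI/SNF lists. For overlaps and the difference between states it takes 5 peaks per direction, of which some are not reported here. Because every matched peak but Arid1a has an FDR of 1 before PPx, the peaks of the difference between states were ranked by the p of the difference. Other genes in the text, such as Mafa, Egfr, Rfx6, Cdkn1b, Sst, Pgk1 and the members of the signalling lists, were chosen after their values were seen.

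Alternatives were an FDR of 0.01, an absolute log2 fold of at least 1, the peaks of lowest mean concentration left out (below the 25th percentile), sex chromosomes left out, genes counted once, promoters within 1 kb, an overlap of 50% of both peaks, genes matched in place of peaks, and identical coordinates. In the list tests with genes counted once, a gene stood by its peak with the smallest FDR and then the smallest p. Added after the data had been seen were a Benjamini-Hochberg adjustment over all listed peaks, folds centred on the median of their table, called peaks of the listed genes with that adjustment, the z test of the difference between states on centred folds, simulated overlaps of lists cut to the observed lengths, lists on promoter peaks only, lists with the trend by bin of mean concentration (10 bins) and promoter class removed, and the gap between promoter and other peaks. Sequence motifs and GC content were not analysed here, since no genome was used.

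The centred calls, the z test and the list test were tested on simulated data, the first 2 with 200 changed peaks; the other steps were not simulated in this way. For 13111 peaks with the standard errors of the table of genotype after PPx, centred calls recovered 11.5% of peaks changed by 1 log2 unit, 90.0% at 2 and 98.0% at 3. For the 7826 peaks of the table before PPx the shares were 13.0%, 80.5% and 97.0%, and for the 12767 peaks of the table of PPx in KO-labelled islets 1.5%, 73.0% and 94.0%. The z test of the difference between states, on 7504 peaks, recovered 2.0%, 56.0% and 94.5% at the same sizes. Both tables were simulated without a shift there, so these shares describe the test on centred folds, not on the deposited ones. Noise was drawn from the implied standard errors. Before PPx their median of 0.43 exceeded the spread of the deposited folds, a standard deviation of 0.38 estimated from quartiles. Of 200 simulated lists of 15 genes on the 13111 peaks, 4.0% of unchanged lists had an unadjusted permutation p under 0.05, as did 100.0% of lists moved by 0.5. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.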

Results

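Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, in pancreatic islets of male mice aged 3 months. All mice carried floxed Arid1a alleles, and Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. Controls carried MIP-rtTA, a doxycycline-dependent activator driven by the mouse insulin promoter, and the KO-labelled mice also carried TRE-Cre, so that doxycycline switches on Cre recombinase in beta cells. Islets were taken at baseline or 6 days after partial pancreatectomy (PPx), an operation after which the remaining beta cells proliferate. The 15 libraries came from 4 control and 3 KO-labelled mice before PPx and from 4 control and 4 KO-labelled mice after PPx. Depth per library is unknown, because the 4 deposited tables give only group means, as log2 normalised reads per peak. Median mean concentrations per table corresponded to 13.7 to 16.2 normalised reads per peak. The same group can have different means for a peak in different tables, and how the tables were scaled is not given in the sources used here, so levels are compared within a table only.

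The gene targeted by Cre stood out in both comparisons of genotype, and its direction is reported first because it bears on the labels. A single Arid1a peak was listed, in exon 9 of 20 (mm10, chromosome 4, 133692981 to 133693581). In the authors' deposited table for islets before PPx, its mean log2 concentration was 1.21 in controls and 5.49 in the group labelled KO, a log2 difference of 4.28 (implied SE 0.83, FDR 0.00187), and the peak was called in 0 of 4 control and 3 of 3 KO-labelled libraries. After PPx the authors' deposited table gave 0.40 and 4.04, a log2 difference of 3.64 (implied SE 0.69, FDR 0.00201), with calls in 0 of 4 and 3 of 4 libraries. Within the KO-labelled mice the same peak was at 5.26 before and 4.04 after PPx in the authors' deposited table, a log2 difference of -1.22 (implied SE 0.47) at an FDR of 0.0584, which missed the threshold. The table comparing controls before and after PPx listed no Arid1a peak. The signal of this single peak of the targeted gene was thus higher, not lower, under the KO label. The labels do not name the floxed exon, so this peak does not by itself check them, and the groups are called KO-labelled wherever a direction is given.

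**Figure D1:**
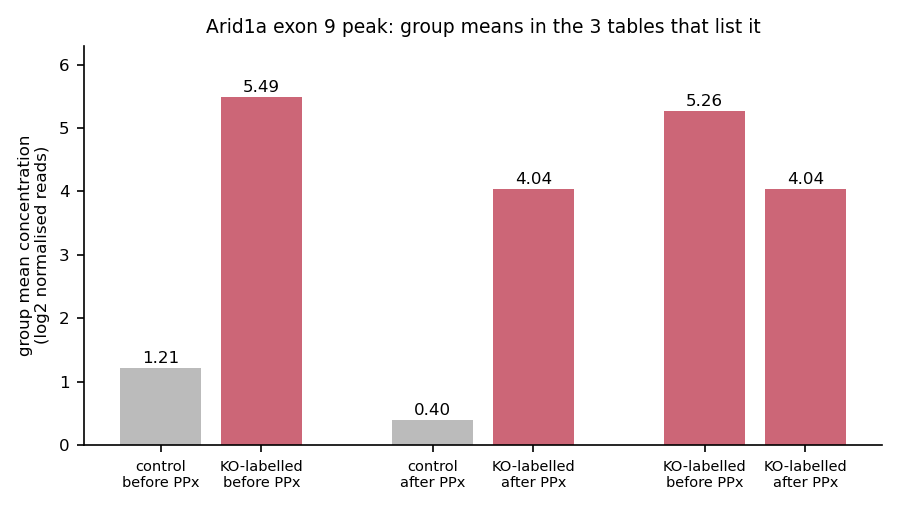
Group mean concentration (log2 normalised reads) of the Arid1a exon 9 peak in the 3 deposited tables that list it, one pair of bars per table; grey bars are control groups and red bars KO-labelled groups, and no error is drawn because the tables give group means only. The KO-labelled bars lie between 4.04 and 5.49 and the control bars at 0.40 and 1.21.

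The comparison of genotypes before PPx asks how Arid1a loss in beta cells alters islet chromatin at rest. The Arid1a exon 9 peak was the only 1 of 7826 peaks to pass an FDR of 0.05, with 1 peak gained and 0 lost by the authors' test. At an unadjusted p under 0.05, 66 peaks were higher and 180 lower. Together they were 3.14% of peaks, below the share of 0.05 that unchanged peaks would give. The median log2 fold over all peaks was 0.00, and the middle 50% of folds ran from -0.27 to 0.24. Genes that passed in the other comparisons had folds on both sides of 0 here. The promoter of Ins1, one of the mouse insulin genes, had a log2 fold of 0.95 (implied SE 0.44, FDR 1) in the authors' deposited table. Intron 2 of Slc30a8, which encodes the zinc transporter of insulin granules, had a log2 fold of -1.45 (implied SE 0.44, FDR 1), with the peak called in 4 of 4 control and 0 of 3 KO-labelled libraries in the authors' deposited table. Promoters of the beta cell transcription factor genes Foxa2 and Nkx6-1 had log2 folds of 0.11 (implied SE 0.47) and -0.24 (implied SE 0.40) in the authors' deposited table, both at an FDR of 1. Of 152 peaks of the fixed gene lists, 1 was called, the Arid1a peak among 9 peaks of SWI/SNF subunits. Of 15 lists tested, 0 passed a permutation test of the median fold adjusted over the lists. The lowest adjusted p was 0.154, for the TGF-beta and activin signalling list, whose 7 peaks had a median log2 fold of 0.48 against 0.00 for random gene sets (unadjusted permutation p = 0.0103; Acvr2a promoter 0.79 and Tgfbr1 promoter 0.48 in the authors' deposited table). Adjusted over the list alone, 1 peak passed in the beta cell identity list and 1 in the SWI/SNF list.

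The comparison of genotypes after PPx asks the same question in islets stimulated to regrow. The deposited signal was higher in the KO-labelled group at 90.3% of listed peaks, and 1297 of 13111 peaks were gained and 11 lost at the authors' FDR of 0.05. A gain of accessibility and a higher signal over background in these libraries cannot be told apart here. The strongest gains by FDR, besides Arid1a, included an intron of Ak5, an adenylate kinase gene, and promoters of genes with varied roles. The Ak5 intron 5 peak had a log2 fold of 2.58 (implied SE 0.48, FDR 0.000605) in the authors' deposited table, 1.97 above the median fold of that table, and was called in 0 of 4 control and 3 of 4 KO-labelled libraries. The promoter of Pttg1, which encodes securin, an inhibitor of sister chromatid separation, rose by a log2 fold of 2.18 (implied SE 0.45, FDR 0.00701) in the authors' deposited table, with calls in 0 of 4 and 4 of 4 libraries. The promoter of Rfxap, a subunit of the complex that drives MHC class II genes, rose by 1.60 (implied SE 0.35, FDR 0.0118) in the authors' deposited table, with calls in 0 of 4 and 4 of 4 libraries. Log2 folds at the same FDR of 0.0154 in the authors' deposited table were 2.08 at the 3' UTR of the sialyltransferase gene St3gal2, 1.59 at the promoter of the proteasome subunit gene Psmd1, 1.34 at the promoter of Thyn1 and 1.49 at the promoter of Ins1 (implied SE 0.35; chromosome 19, 52263934 to 52264534). The MIP transgene carries insulin promoter sequence, and reads of the transgene and of the Ins1 promoter were not separated here.

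The 11 lost peaks held 2 genes that the naming rule takes. Exon 61 of Pkhd1, the fibrocystin gene, fell by 1.16 (implied SE 0.37, FDR 0.0345) in the authors' deposited table, with calls in 4 of 4 control and 1 of 4 KO-labelled libraries. A distal peak assigned to Ndufb3, a subunit gene of respiratory complex I, fell by 1.19 (implied SE 0.43, FDR 0.0469) in the authors' deposited table, with calls in 4 of 4 and 0 of 4 libraries, and did not pass when adjusted over all listed peaks (adjusted value 0.0653). The other 9 lost peaks were assigned to predicted genes with Gm symbols, among them Gm20812 and Gm21860 on chromosome Y and Gm22464 on chromosome X.

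The median log2 fold over all peaks after PPx was 0.61, with 90.3% of peaks above 0, and 4331 peaks were higher and 69 lower at an unadjusted p under 0.05. Centred on that median, 2 gained peaks were left, those of Arid1a and Ak5, against 49 lost ones, in place of 1297 gained and 11 lost as deposited. Every other gained peak named here therefore exceeded the shift of the whole table by less than the test could call. Centred calls recovered only 11.5% of simulated peaks changed by 1 log2 unit, so their low number does not exclude gains of that size beyond the shift.

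**Figure D2:**
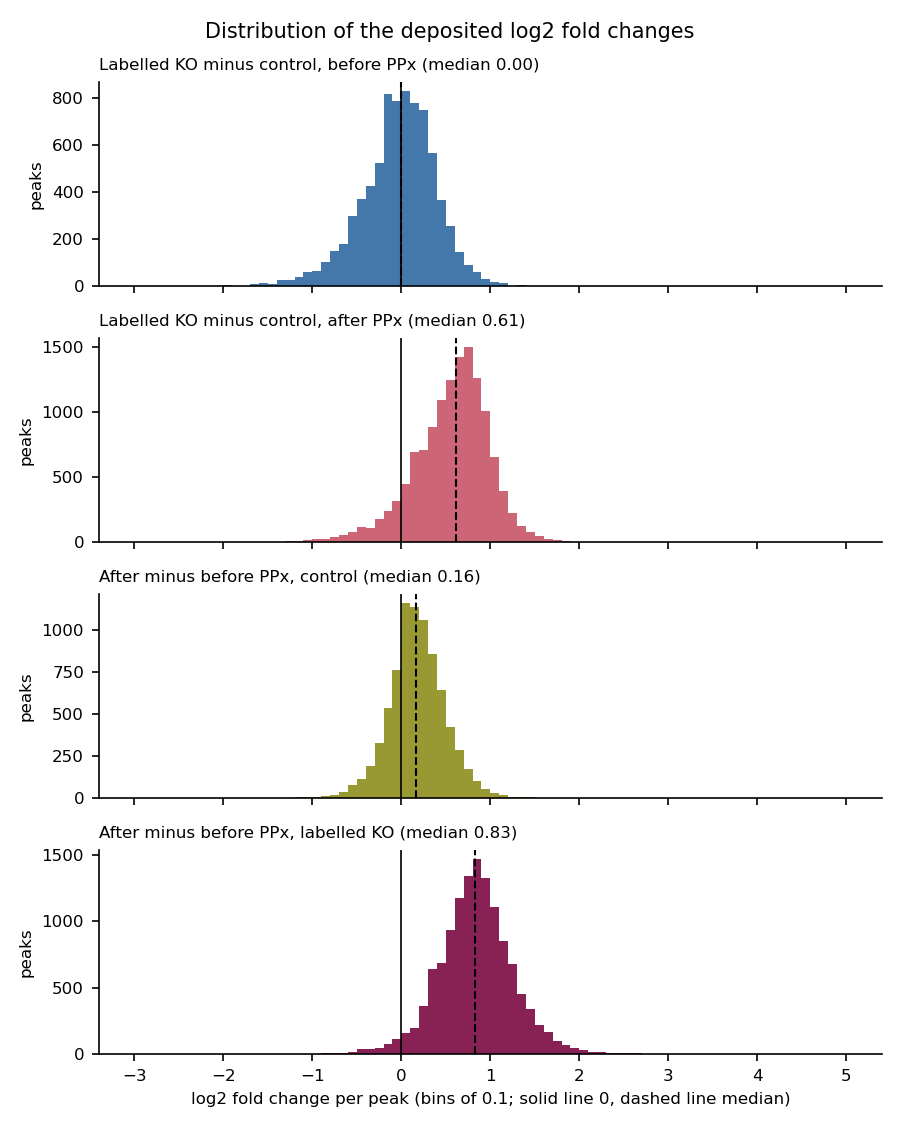
Histograms of the deposited log2 fold per peak in bins of 0.1, one panel per comparison, with the number of peaks on the y axis; the solid line marks 0 and the dashed line the median. The medians are 0.00 and 0.61 for KO-labelled minus control before and after PPx, and 0.16 and 0.83 for after minus before PPx in control and KO-labelled islets.

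Beta cell identity genes were among those gained after PPx: 4 of 25 listed peaks rose, 0 fell and 21 did not pass. Over the whole comparison 9.98% of peaks were called, nearly all as gained, and 14.3% of promoter peaks were gained. Counts near these shares are therefore not particular to a list. In the authors' deposited table the log2 folds were 1.49 at the Ins1 promoter, 1.15 (FDR 0.0329) at Foxa2, 1.05 (FDR 0.0360) at Nkx6-1 and 1.01 (FDR 0.0492) at Rfx6, a factor needed for islet development. The promoter of Mafa, an activator of insulin transcription, had a log2 fold of 0.38 (FDR 0.455) in the authors' deposited table, which lies below the median of all peaks. Of 18 peaks of EGF and neuregulin ligands and their ERBB receptors 1 rose, at the promoter of the ligand gene Btc, by 0.90 (implied SE 0.33, FDR 0.0487) in the authors' deposited table. The promoter of Egfr had a log2 fold of 0.42 (implied SE 0.37, FDR 0.338) in the authors' deposited table, also below the median of all peaks. Of 31 peaks of cell cycle drivers 2 rose, at the cyclin promoters of Ccne2 by 0.93 (FDR 0.0396) and Ccna2 by 0.98 (FDR 0.0493) in the authors' deposited table. Of 8 peaks of cell cycle inhibitors 4 rose, with log2 folds in the authors' deposited table of 1.14 at Cdkn2c, 0.94 at Cdkn2d, 1.01 at Cdkn2b and 0.89 at Cdkn1b, all promoters of genes for inhibitors of cyclin-dependent kinases. Arid1a was the 1 called peak among 15 of SWI/SNF subunits. Many of these calls lay near the threshold: adjusted over all listed peaks, the gained counts were 2 for beta cell identity (without Nkx6-1 and Rfx6), 0 for EGF and neuregulin, 0 for cell cycle drivers, 1 for cell cycle inhibitors (Cdkn2c) and 1 for SWI/SNF subunits.

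Peaks of further fixed lists were gained in part. Over all lists 30 of 249 peaks were called, against 9.98% of all peaks of the comparison. Among 27 peaks of ERBB-MAPK signalling and feedback 4 rose, with log2 folds in the authors' deposited table of 1.44 at Dusp4, 1.06 at Spry2, 1.00 at Etv5 and 1.01 at Sos1. The TGF-beta and activin list had 3 of 9 peaks gained, with log2 folds in the authors' deposited table of 1.09 at Skil, 1.08 at Tgfbr1 and 1.03 at Smad2. Adjusted over all listed peaks, gained peaks numbered 5 for ERBB-MAPK signalling and 2 for TGF-beta and activin, and over all lists 14 in place of 30. At the authors' FDR of 0.01 the called list peaks numbered 1. Gained peaks numbered 2 of 19 for insulin and IGF signalling, 1 of 9 for prolactin receptor signalling, 2 of 11 for the unfolded protein response and 4 of 12 for the interferon and NF-kB response, or 1, 0, 1 and 0 adjusted over all listed peaks. The list of genes normally kept off in beta cells had 0 of 7 peaks gained, the AP-1 factors had 0 of 12 and the progenitor and dedifferentiation list had 1 of 7, or 0 adjusted over all listed peaks. Among markers of other cells, 1 of 5 delta and PP cell peaks was gained, a distal peak of the somatostatin gene Sst with a log2 fold of 1.12 (FDR 0.0294) in the authors' deposited table. The count was 0 of 12 for alpha cells, 0 of 2 for acinar cells, 0 of 4 for ductal cells, 0 of 9 for endothelial cells, 0 of 4 for stellate cells and fibroblasts, 0 of 3 for leukocytes and 0 of 1 for Schwann cells. These totals include peaks of low concentration that the deposited FDR could not call, such as the Schwann cell peak and the endothelial peaks of Cdh5. Adjusted over the list alone, the peaks that passed numbered 5 for beta cell identity, 0 for EGF and neuregulin, 0 for cell cycle drivers, 4 for cell cycle inhibitors, 6 for ERBB-MAPK signalling, 6 for the unfolded protein response, 5 for the interferon and NF-kB response and 4 for TGF-beta and activin signalling. That count was 2 for genes normally kept off in beta cells and 1 each for the progenitor, SWI/SNF, insulin and IGF, prolactin, delta and PP cell and acinar lists, and 0 for the remaining lists. As background to these counts, 33.6% of all peaks of the comparison had an unadjusted p under 0.05 in the authors' test. By the permutation test of medians 0 of 20 lists passed, the lowest adjusted p being 0.52. The beta cell identity median was 0.67 against 0.58 for random sets (adjusted permutation p = 0.697), that of cell cycle inhibitors 0.86 against 0.64 (adjusted p = 0.52) and that of endothelial markers 0.26 against 0.58 (adjusted p = 0.52). Counting each gene once, the endothelial list passed, with a median of 0.08 against 0.67 (adjusted permutation p = 0.0374). Here each gene, in the list and in the random sets, stood by its peak with the smallest FDR and then the smallest p. For Cdh5 that kept the peak at -0.54 and left out those at 0.08, 0.41 and 0.34. The pass therefore depends on how the peaks were picked. On all 9 peaks it did not pass either as deposited or with the trend by concentration and promoter class removed, where its median was -0.32 against 0.00 for random sets (unadjusted permutation p = 0.0336, adjusted p = 0.56).

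**Figure D3:**
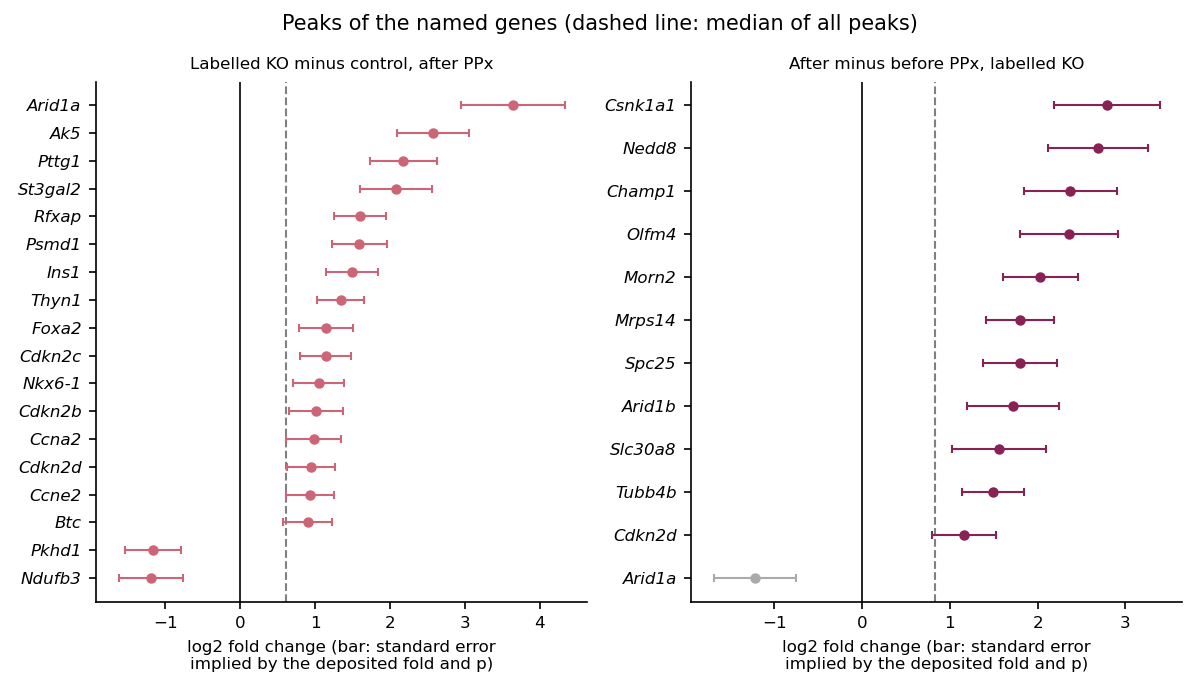
Log2 fold of the peaks of the named genes after PPx by genotype (left) and after against before PPx in KO-labelled islets (right); points are the deposited folds, bars the standard errors implied by the deposited fold and p, and the dashed line the median of all peaks (0.61 and 0.83). Pkhd1 and Ndufb3 lie below 0 on the left, and the grey Arid1a point on the right, at -1.22, did not pass the test.

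Gained peaks after PPx lay mostly at promoters. Of the 1297 gained peaks, 1155 (89.1%) were annotated as promoters, against 0 of 11 lost peaks (two-sided Fisher's exact test across peaks, p = 4.05e-11) and 68.3% of the other peaks at concentrations where the authors' test made calls. Promoter peaks had a median log2 fold of 0.71 and other peaks 0.38, a gap of 0.33 (SE 0.0190), which was 0.25 (SE 0.0182) within 10 equal bins of mean concentration. Before PPx the gap was 0.16 (SE 0.0156), or 0.14 (SE 0.0188) within bins, with promoter peaks at 0.04 and other peaks at -0.12. Promoters had the higher median on 19 of 21 chromosomes before PPx and on 21 of 21 after it. Standard errors of the gap come from leaving out each chromosome in turn, so they hold no spread between libraries. Peaks are not independent replicates, so these tests describe the listed peaks. The gap was examined after the folds had been seen.

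**Figure D4:**
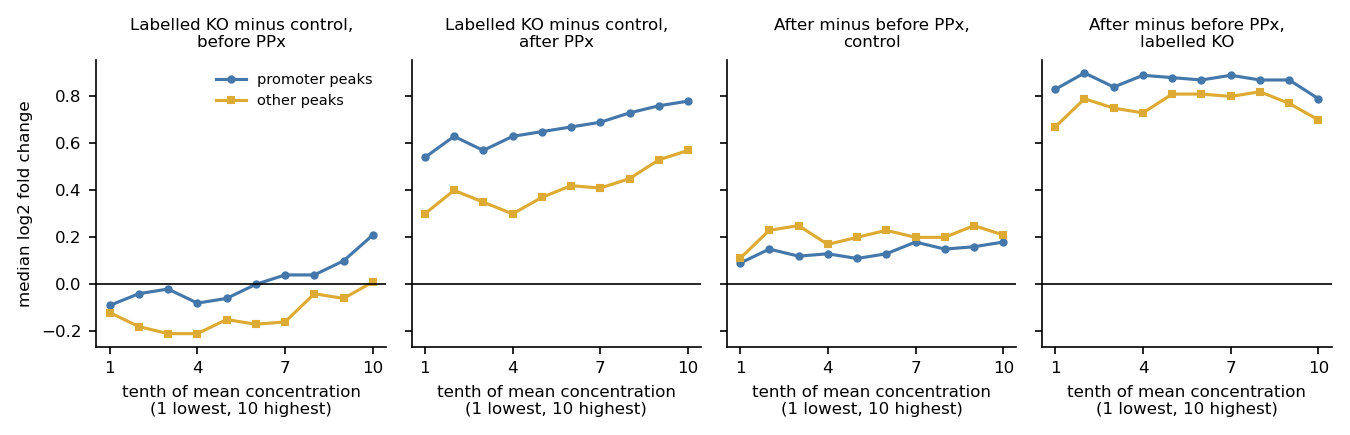
Median log2 fold of promoter peaks (blue) and other peaks (yellow) within 10 equal bins of mean concentration, from 1 (lowest) to 10 (highest), one panel per comparison on a shared y axis. Within bins, the mean gap between promoter and other peaks is 0.14 and 0.25 for KO-labelled minus control before and after PPx, and -0.06 and 0.10 for after minus before PPx in control and KO-labelled islets.

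The comparison of control islets after and before PPx asks what PPx does to islet chromatin in mice without Cre, as labelled. No single peak could be called: 0 of 8070 passed the authors' test at an FDR of 0.05, and the lowest FDR was 0.619. At an unadjusted p under 0.05, 196 peaks were higher and 8 lower. Together they were 2.53% of peaks, below the share of 0.05 that unchanged peaks would give. The median log2 fold was 0.16, and 72.8% of peaks lay above 0. Pttg1 and Rfxap, both gained by genotype after PPx, had promoter folds below 0 in these controls. The Pttg1 promoter had a log2 fold of -1.51 (implied SE 0.48, FDR 0.999) and was called in 3 of 4 libraries before and 0 of 4 after PPx in the authors' deposited table. The Rfxap promoter had a log2 fold of -1.03 (implied SE 0.36, FDR 0.999) and was called in 4 of 4 and 0 of 4 libraries in the authors' deposited table. Both comparisons use the 4 control libraries taken after PPx, which ties their signs. Cell cycle genes lay near the median of the table, with log2 folds of 0.06 at Ccna2, 0.19 at Ccne2 and 0.21 at Cdkn2d in the authors' deposited table. Of 16 lists tested 0 passed the permutation test, and adjusted over the list alone 0 peaks passed in any list. The delta and PP cell markers came closest (3 genes, median log2 fold 0.70 against 0.18 for random sets, unadjusted permutation p = 0.00314, adjusted p = 0.0502), through Bche at 1.10 and Ptprz1 at 0.69 and 0.72 rather than Sst at 0.10, as log2 folds in the authors' deposited table. With the trend by concentration and promoter class removed that list passed, at a median of 0.59 (adjusted permutation p = 0.0275), and with each gene counted once and the trend kept it did not, at a median of 0.72 (adjusted permutation p = 0.232).

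In KO-labelled islets the same comparison of after with before PPx gave a broad rise of the deposited signal, with 97.1% of peaks above 0. At the authors' FDR of 0.05, 951 of 12767 peaks were gained and 0 lost. The lowest FDR, 0.00770, was shared by 4 peaks of the authors' deposited table. They were the promoters of Nedd8, a ubiquitin-like modifier gene, at a log2 fold of 2.69 (implied SE 0.57), of Morn2 at 2.03 (implied SE 0.43) and of the mitochondrial ribosomal gene Mrps14 at 1.80 (implied SE 0.39), and a distal peak of the kinase gene Csnk1a1 at 2.79 (implied SE 0.60), all in the authors' deposited table. The promoter of Champ1, which acts in chromosome alignment, rose by 2.37 (implied SE 0.53, FDR 0.0114) in the authors' deposited table. At an FDR of 0.0192 the authors' deposited table listed log2 folds of 1.80 at the promoter of the kinetochore gene Spc25, 1.49 at that of the tubulin gene Tubb4b and 2.36 in intron 2 of Olfm4.

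Among listed genes in KO-labelled islets, 1 of 24 beta cell identity peaks rose, in intron 2 of Slc30a8 by a log2 fold of 1.56 (implied SE 0.54, FDR 0.0484) in the authors' deposited table. Of 9 peaks of cell cycle inhibitors 1 rose, at the promoter of Cdkn2d by 1.16 (FDR 0.0386) in the authors' deposited table, and of 17 peaks of SWI/SNF subunits 1 rose, in intron 8 of Arid1b, the paralogue of Arid1a, by 1.72 (implied SE 0.52, FDR 0.0353) in the authors' deposited table. The EGF and neuregulin list had 0 of 18 peaks gained and the cell cycle drivers 0 of 30. Called list peaks numbered 14 of 247, or 9 when adjusted over all listed peaks, where the Slc30a8 call was lost, and 0 at the authors' FDR of 0.01. Over the whole comparison 7.45% of peaks were called, and 39.4% had an unadjusted p under 0.05 in the authors' test. By the permutation test 0 of 19 lists passed (lowest adjusted permutation p = 0.566). Adjusted over the list alone, 7 peaks passed for the unfolded protein response, 5 for ERBB-MAPK signalling, 4 for the interferon and NF-kB response, 3 for insulin and IGF signalling, 2 for endothelial markers, 1 for cell cycle inhibitors and 1 for SWI/SNF subunits, and 0 for beta cell identity, EGF and neuregulin and cell cycle drivers. That count was 1 each for the alpha, acinar, ductal and leukocyte marker lists and 0 for the remaining lists. Several of these genes had lower values in KO-labelled than in control islets before PPx, with log2 folds in the authors' deposited table of -0.99 at Morn2, -0.74 at Mrps14, -0.64 at Champ1, -1.53 at Olfm4 and -0.34 at Spc25, none passing. The 2 comparisons share the KO-labelled libraries taken before PPx, which ties their signs.

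The median log2 fold over all peaks of KO-labelled islets was 0.83, with 97.1% of peaks above 0, and 5027 peaks were higher and 3 lower at an unadjusted p under 0.05. Centred on that median, 0 gained and 0 lost peaks passed, in a test that recovered 1.5% of simulated peaks changed by 1 log2 unit and 73.0% at 2. The simulation drew its noise from the implied standard errors, with a median of 0.49. The deposited folds spread less, with a standard deviation of 0.37 estimated from their quartiles, so these shares may not hold for the deposited folds. Promoters made up 782 of the 951 gained peaks (82.2%), against 68.2% of the other peaks at concentrations where calls were made (two-sided Fisher's exact test across peaks, p = 8.42e-21). No lost peaks existed for the planned test of gained against lost.

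The overlap of comparisons asks whether the same peaks moved. Of 7504 peaks listed in both comparisons of genotype, the 1 gained before PPx, at Arid1a, was also gained after it (0.156 expected of independent lists, Fisher's exact p = 0.156), and Pearson's r of the folds across peaks was 0.29. Folds after against before PPx in control and in KO-labelled islets had an r of 0.01 across 7535 shared peaks, with 0 calls in common since controls had 0. Peaks are not independent replicates, and no p is given for these correlations. The genotype comparison after PPx and the PPx comparison in KO-labelled islets share 4 libraries. They had 321 gained peaks in common, 288 of them at promoters, against 101.0 for independent lists of those lengths. Simulated unchanged groups with the same sharing called 46.3 and 28.3 gained peaks on average, 2.18 of them shared. In the same simulations, lists of the observed lengths, cut by rank, shared 320 peaks on average (290 to 351), near the observed 321. This reading by length was added after the overlap had been seen. The covariance of the folds was 0.0596, below the simulated 0.114, so the simulated folds were tied more strongly than the deposited ones. The simulations therefore cannot decide whether the overlap exceeds what the shared libraries give, and the shared group was not split here. Peaks gained in both included a distal Csnk1a1 peak, with log2 folds of 1.64 and 2.79, and the promoters of Tatdn2 (1.18 and 1.62), Psmd1 (1.59 and 1.92), Ninl (1.31 and 1.59) and Agtpbp1 (1.27 by genotype) in the authors' deposited tables.

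The log2 fold between KO-labelled and control islets was higher after than before PPx by a median of 0.64 over 7496 peaks, and 0 single peaks passed. That difference is the shift of the whole table after PPx, as the median folds of these peaks were 0.00 before and 0.66 after it, and with each table centred on its median it was 0.03. A z test on the difference of the deposited folds, adjusted by Benjamini-Hochberg, had a lowest adjusted p of 0.0934, and 1085 peaks (14.5%) had an unadjusted p under 0.05, 1077 of them upward and 8 downward. With both tables centred, 0 of the 7496 peaks passed the z test, at a lowest adjusted p of 0.51. Unadjusted p under 0.05 stood beside 59 upward and 61 downward differences, or 1.6% of peaks, below the share of 0.05 that unchanged peaks would give. The Psmd1 promoter went from a log2 fold of -1.15 to 1.59 in the authors' deposited tables, a difference of 2.74 (SE 0.63, adjusted p = 0.0934). Differences upward included those at Ninl (1.96) and the splicing regulator gene Mbnl1 (2.23), each at an adjusted p of 0.15. The downward differences with the lowest p were -1.85 at Fez2, -1.82 at Speer4cos, -1.18 at Ndufb3 and -1.20 at Cntn5, together with Pkhd1 exon 61, which went from -0.16 to -1.16 in the authors' deposited tables, with adjusted p from 0.304 to 0.37.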

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

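The adjustment over all listed peaks, the centring on the median, the lists on promoter peaks only or with the trend removed, the simulated overlaps of equal length and the promoter gap were tests chosen after the results were seen; the other settings were fixed earlier. At an FDR of 0.01, gained peaks by genotype after PPx went from 1297 to 3 and lost peaks from 11 to 0, gained peaks by PPx in KO-labelled islets from 951 to 5, of which 60.0% were promoters, and the gained peaks these comparisons shared from 321 to 0, since a stricter threshold removes calls by construction; called peaks of listed genes went from 30 to 1 and from 14 to 0 (14 and 9 with the adjustment over all listed peaks). With an absolute log2 fold of at least 1, 840 gained peaks were left by genotype after PPx. Adjusted over all listed peaks, the gained counts were 541 by genotype after PPx and 573 by PPx in KO-labelled islets; more peaks enter that adjustment. Centred on the median, gained peaks numbered 2 and 0 in those tables and lost peaks by genotype after PPx 49, since centring removes the shift of the whole table. With genes counted once, 1 list passed by genotype after PPx, the endothelial markers, and with the trend by concentration and promoter class removed, 1 list passed by PPx in controls, the delta and PP cell markers; the cause was not tested. In 81 other recalculations of these counts and shares the value stayed within 1.5 times or within its spread. Many of them were counts of 0 that stayed 0 or the Arid1a call kept alone, and a count of 0 cannot fall at a stricter threshold. Their number therefore says little about the gained counts of the comparisons that hold the KO-labelled libraries taken after PPx. Of the named peaks, 23 stayed on their side of the threshold with the adjustment over all listed peaks and 8 lost their call (Ndufb3, Nkx6-1, Btc, Ccne2, Ccna2, Cdkn2d and Cdkn2b by genotype after PPx, Slc30a8 by PPx in KO-labelled islets), and with centring 6 stayed and 25 lost it; none changed sign. No paired analysis was possible because the groups share no sample numbers and the tables give group means. For the same reason leaving out each replicate, other splits of the samples, and the settings for counts or pseudocounts were not run, and neither were peaks within 10 kb of a transcription start site (no distance was used), the share of promoters at an FDR of 0.01 after PPx by genotype against lost peaks (0 lost calls were left) and motifs. Depth per library is unknown, so detection limits were not estimated.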

Other observations

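All tests in this part were chosen after the main results were seen. For ribosomal protein promoters and housekeeping gene families, the predictions were written before the values they concern were seen. Both address patterns already seen in the main results. Promoters of housekeeping genes took part in the gain after PPx, in which 1155 of 8050 promoter peaks (14.3%) were gained by genotype, or 18.8% of the 6156 at concentrations where calls were made. By genotype after PPx 11 of 57 promoter peaks of cytosolic ribosomal protein genes were gained, 9 of 34 of mitochondrial ribosomal protein genes, 4 of 23 of proteasome subunit genes, 6 of 20 of spliceosome genes and 5 of 28 of complex I genes, or 17.4% to 30.0% per family. Among other families the counts were 33 of 180 for zinc finger genes, 15 of 107 for solute carriers, 5 of 34 for Rab GTPases and 8 of 35 for histones. A hypothesis that the housekeeping families gained more than other promoters of like signal strength was tested with 9 families per table. It found 0 housekeeping families with a passing residual in both tables that hold the KO-labelled libraries taken after PPx, where the lowest adjusted permutation p was 0.509 by genotype and 0.617 by PPx.

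The promoter of Pgk1, a glycolytic enzyme gene on chromosome X, had the reverse order of most peaks after PPx. Its mean log2 concentration was 8.76 in controls and 6.68 in KO-labelled islets in the authors' deposited table, a log2 fold of -2.08 with a deposited p of 1. In controls it went from 4.84 before to 8.81 after PPx in the authors' deposited table, a log2 fold of 3.97, also with a deposited p of 1, and in KO-labelled islets from 4.84 to 6.67 (FDR 0.0503). These p do not follow from the folds, and no call is drawn from them. Peaks on chromosome Y had a median log2 fold of 0.13 by genotype after PPx, against 0.61 on autosomes and 0.72 on chromosome X. A distal peak of Gm21860 on chromosome Y had a log2 fold of 1.30 (FDR 0.619) by PPx in controls and -1.25 (FDR 0.0341) by genotype after PPx in the authors' deposited tables.

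Folds lay above 0 at nearly every peak in both tables that hold the KO-labelled libraries taken after PPx. The tables argue against an opening limited to some classes of genes as the whole source, since ribosomal protein promoters, of genes used by all cells, had median folds of 0.71 and 0.94 by genotype and by PPx, against 0.71 and 0.86 for all promoters. This does not speak to an opening of some classes on top of a shift shared by all peaks, which would lift these promoters as well. One difference equal at all peaks, as the whole source, would give no gap, but promoters exceeded other peaks by 0.33 (SE 0.0190) by genotype and by 0.09 (SE 0.0104) by PPx. These standard errors come from leaving out each chromosome in turn and hold no spread between libraries. In controls, with 0 calls, the gap by PPx was -0.05 (SE 0.0178), so a gap of the size seen by PPx in KO-labelled islets does not decide this. Other peaks had medians of 0.38 and 0.77, so a part shared by all peaks stays open, and the fall of gained calls on centring, to 2 and 0, does not decide how large it is, because centred calls recovered 11.5% and 1.5% of simulated peaks changed by 1 log2 unit. Higher signal over background in these libraries could be a source and cannot be told apart. Peaks were called in 71.4% of KO-labelled libraries after PPx on average, against 40.7% of control libraries after PPx. In the table of PPx in KO-labelled islets the shares were 72.8% after and 46.7% before PPx. A true gain of accessibility would give such shares as well. They also depend on which peaks a comparison lists. By PPx in controls, the control libraries after PPx stood at 61.1%, and by genotype before PPx the KO-labelled libraries stood at 70.5%. The median fold rose by 0.38 from the lowest to the highest of 10 bins of concentration by genotype (SE 0.0540), but by 0.06 by PPx (SE 0.0900). Without these libraries, it rose by 0.3 by genotype before PPx (SE 0.0298) and by 0.1 by PPx in controls (SE 0.0405). The rise by genotype was thus not particular to the KO-labelled libraries taken after PPx. A genome-wide gain of accessibility in KO-labelled islets after PPx stays open as an untested biological explanation, because neither library values nor a spike-in were used here.

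The Arid1a exon 9 peak was higher under the KO label in both comparisons of genotype. The shift of all peaks after PPx is argued against as its source, since before PPx the peak lay 4.28 above the median of its table. An exchange of the control and KO labels cannot be told apart: no further Arid1a peak fixes the genotype, and the control-labelled group was at 5.15% of the KO-labelled signal before and 8.02% after PPx, with the peak called in 0 of 4 control libraries each time, so these values lie near the floor and need not be signal left after Cre. A hypothesis is that the peak may come from exon DNA that Cre cut out and that stayed accessible, which would thin out as cells divide after PPx. Relative to its table the peak was at -2.05 after PPx (SE 0.47, unadjusted p of the z test 1.2e-05). The adjusted p of 0.153 over 12765 peaks missed the threshold set for this hypothesis. That adjustment covers all peaks, though the hypothesis concerns 1 peak, so the miss does not speak against a fall of this peak. The hypothesis was written after the results were seen, and a fall alone does not settle the source, so this too stays open. The labels do not name the floxed exon.

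Promoter peaks lay further toward KO-labelled islets than other peaks. A single scaling factor per library is argued against, because it moves all peaks alike and the gap was 0.16 before and 0.33 after PPx. Each was over 2 standard errors above 0, computed across chromosomes and without spread between libraries. Signal strength as the whole source is argued against as well, since gaps of 0.14 and 0.25 were left within 10 bins of concentration. Library differences unrelated to genotype could still give such gaps: the smaller genotype gap exceeded the larger gap within a genotype by only 0.04 (SE 0.0245), so the sources cannot be told apart. That standard error holds no spread between libraries. It also treats the gaps as independent, though both comparisons use the KO-labelled libraries taken before PPx. An effect of genotype on promoters stays open as a hypothesis, and GC content was not tested.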
